A study of Homo sapiens with 2 samples.

How the data were processed

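RNA-seq of polyadenylated RNA from Tu212 cells was analysed, with 1 library for the vector control and 1 for PRMT5 overexpression, grouped by the genotype given in the labels. Total RNA was isolated with TRIzol and libraries were made with an NEB kit for Illumina sequencing, per the labels' protocols; whether the kit kept strand is not given in the sources used here. CASAVA 1.8, HISAT2 2.1.0, StringTie 1.3.4b and edgeR, with the builds GRCh38 and hg38, are named per the submitters' processing notes, without their roles. The deposited table gave each of 58302 genes a raw count and an FPKM value per library, with gene symbol, gene type and position. The table's raw counts were used as deposited by the authors. Among 11478 genes with over 100 reads in both libraries, the deposited FPKM equalled the count divided by the total count and by 1 fixed length per gene in 100% of genes, within 1%. That length had a median of 1.55 times the merged exon length in GENCODE release 29, so levels in FPKM were not compared between genes. The authors' table held no fold changes or p-values of its own among the columns used here, and 0 per-sample columns were left unused.

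Rows of the same symbol were summed, since 221 symbols stood on more than 1 row, with 1612 rows beyond the first of each. Counts were scaled by TMM (edgeR 4.0.16 in R 4.3.3; factors 1.01 for the vector control and 0.990 for PRMT5 overexpression) and expressed as log2 CPM with a prior count of 1. The log2 ratio is PRMT5 overexpression minus vector control, among genes with 10 or more reads in at least 1 library. Higher and lower mean a log2 ratio of at least 1 or at most -1. No test across genes was run and no p-value is given, because genes are not replicates. Counting intervals are exact binomial (Clopper-Pearson) intervals at 95%, scaled by the library sizes. A gene with 0 reads in a library was set against a floor of 3 reads, which is 0.210 CPM in the vector control and 0.152 CPM in PRMT5 overexpression. Reads are not independent molecules, so intervals and floors cover counting error only. The deeper library had 1.41 times the reads of the other.

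Before the data were examined, 46 gene lists with 1135 entries were fixed, of which 1128 matched a gene in the table by current or older symbol. The median log2 ratio of the members past the floor was set as a percentile among 10000 lists of the same size, drawn with replacement from 20 equal bins of mean log2 CPM, as a description of these libraries. A list stood apart when its median lay outside the central 95% of random medians with 5 or more members, and 2 lists had too few members. Genes were named by a rule fixed at the same time: PRMT5; the 12 largest and 12 smallest log2 ratios among protein-coding genes at 5 CPM or more in at least 1 library; up to 4 members per list at 1.5-fold or more past that floor; 2 members nearest the median for lists that stood apart; and the 5 genes with the highest mean. The report gives a part of the genes so named, and some items are not reported here. PRMT5-AS1, FTH1, CCDC92, LRRC75A-AS1, COL1A2, DCN, PDGFRB, MFAP5, ITGAM, VWF and ERG were added after their values were seen.

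Gene positions in the table were compared with GENCODE release 29 (GRCh38). Of the gene IDs, 58039 were found there and 56647 had the same start and end. Genes that share exon bases on either strand, with 10 or more reads in at least 1 library, are called exon-sharing genes. Named genes were also searched for shared sequence in transcripts of all genes other than their exon-sharing genes. The measure was the share of 50-base stretches of the longest transcript, taken every 10 bases, that occur there. Overlapping genes with fewer reads than the floor were not left out. The share was 79.3% for TUBB3, 46.9% for KRT6B, 41.4% for RAB43, 35.5% for ISY1-RAB43 and 23.1% for RPLP0, so their reads are uncertain. It was 16.7% to 19.6% for PHLDA3, MT-ND6, HSP90AB1, AKR1B10 and CCL5.

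The procedure was tested on simulated data, in which 200 genes of a simulated PRMT5 overexpression over vector control pair with 17764 genes were changed. All 100 genes changed 4-fold and 55% of 100 genes changed 2-fold reached 2-fold, and 0 of 13002 unchanged genes with a mean of 50 or more reads did. All 4 simulated lists of 25 genes shifted by 1.2-fold stood apart, as did 5.5% of 200 unchanged lists. The simulated pair held no difference between cultures and no genes that vary together, so these rates hold for counting error alone. Alternatives were prior counts of 0.1 and 5, DESeq2 1.42.0 size factors, no floor, a floor of 50 reads, the highest row per symbol, protein-coding genes only, a threshold of 1.5-fold, deposited FPKM with a pseudocount of 1, unmatched random lists and the mean of list members. Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.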

Results

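Polyadenylated RNA was sequenced from Tu212 cells, an epithelial-derived line that is used as a model of head and neck squamous carcinoma. The cells had been treated for 48 h with a pEZ plasmid that encodes PRMT5 or with the pEZ vector alone, and 1 library was made per group. The vector control library held 14119997 reads assigned to genes and the PRMT5 overexpression library held 19908258. Reads were found on 25598 and 26388 genes, respectively. With 1 library per group there is no replicate check of any difference below, and the values describe these libraries and not the condition. Intervals are 95% Clopper-Pearson intervals and cover counting error only.

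The comparison asked which transcripts differed when PRMT5 was overexpressed. PRMT5, the arginine methyltransferase that places symmetric dimethyl marks on histones and on splicing proteins, was 2.02-fold higher in the library labelled PRMT5 overexpression, at 293 CPM against 145 CPM in the vector control. Its log2 ratio was 1.01, with an interval of 0.94 to 1.09, from 5770 and 2068 reads. The gene (ENSG00000100462) lies on the minus strand of chromosome 14 from 22920511 to 22929585 in GRCh38. The antisense gene PRMT5-AS1 shares exon bases with it and held 61 and 21 reads, and reads on the shared bases could be told apart only by strand. Once summed with PRMT5-AS1, PRMT5 again had a log2 ratio of 1.01. Of 4118 genes with a mean of 1000 or more reads, 16 had a log2 ratio at or above that of PRMT5, PRMT5 included. The list of 10 proteins that bind PRMT5 had a median log2 ratio of 0.08, at the 92.1 percentile of matched random lists, and 9 measured members of the arginine methyltransferase family had a median of 0.06, at the 85.4 percentile.

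Among 17777 genes with 10 or more reads in at least 1 library, 516 were at least 2-fold higher and 344 at least 2-fold lower in the PRMT5 overexpression library. Most of these genes had few reads. Among 13282 genes with a mean of 50 or more reads, 106 were higher and 107 lower, and 94.9% of those genes lay within 1.5-fold. MYC, the transcription factor that drives growth and cell cycle entry, was 14.8-fold lower, at 7.71 CPM against 114 CPM. Its log2 ratio was -3.88, with an interval of -4.14 to -3.65. MYC (ENSG00000136997) lies on chromosome 8 from 127735434 to 127741434 and shares no exon base with another counted gene. Whether reads at the MYC locus were counted alike in both libraries was not analysed here.

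Other protein-coding genes among the 12 lowest that share no exon base with a counted gene were FAM110A, the zinc finger gene ZNF264 and the splicing regulator MBNL3, with log2 ratios of -3.29, -3.18 and -2.78. The 12 highest included DAG1, which encodes the laminin receptor dystroglycan. DAG1 was 7.36-fold higher, at 145 CPM against 19.8 CPM, with a log2 ratio of 2.88 and an interval of 2.70 to 3.06. AIF1L, ZNF778, TMEM164 and the chaperone cofactor DNAJB5, which share no exon base with a counted gene either, had log2 ratios of 2.26, 2.19, 2.06 and 1.96. ZNF664 had a log2 ratio of 2.35 and shares exon bases with CCDC92.

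Several of the most extreme genes are uncertain because they overlap other counted genes. The readthrough gene ISY1-RAB43 had 206 reads in the vector control library and 0 in the other. It was 94.9-fold lower against a floor of 3 reads in that library, with a counting interval up to a log2 ratio of -6.26. RAB43 was higher, with a log2 ratio of 2.51. Once summed with the genes that share their exons, ISY1-RAB43 was at 0.82 and RAB43 at 1.33. AL136295.1 had 0 and 165 reads and overlaps several counted genes. It was 39.8-fold higher against a floor of 3 reads in the vector control library, with a counting interval from a log2 ratio of 5.00. BEST1, which overlaps the ferritin heavy chain gene FTH1, had a log2 ratio of 4.27 from 48 and 1305 reads, where FTH1 held 18139 and 25735. LRRC75A had a log2 ratio of -4.37 from 136 and 8 reads, where its antisense gene LRRC75A-AS1 held 4516 and 6124.

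**Figure D1:**
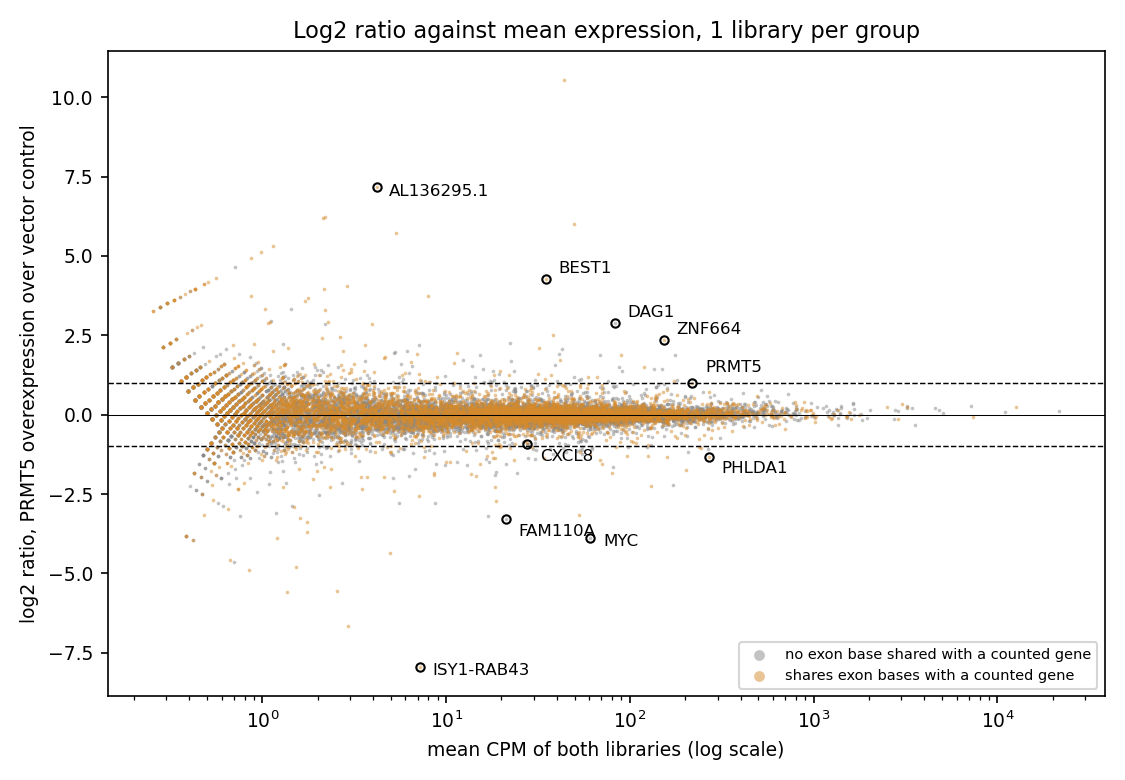
Each point is a gene with 10 or more reads in at least 1 library, without Y-linked genes and XIST. The horizontal axis gives the mean CPM of both libraries on a log scale and the vertical axis the log2 ratio of PRMT5 overexpression over vector control. Dashed lines mark log2 ratios of 1 and -1, orange points share exon bases with another counted gene, and PRMT5 lies at 1.01 and MYC at -3.88.

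The gene lists fixed before the data were examined were described by their median log2 ratio. Of 44 lists with 5 or more measured members, 14 had a median outside the central 95% of 10000 random lists matched on expression. If genes varied independently, 2.2 lists would do so by chance. Genes of a list may vary together between any cultures, which the random lists leave out. The numbers 14 and 2.2 therefore do not measure an excess over chance. There were 7 lists that stood apart on each side.

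The median of the NF-kB target cytokines and chemokines stood apart below 0. Of 26 measured members, 19 had a log2 ratio below 0, and 8 were lower and 1 higher by 1.5-fold or more. The median was -0.28, at the 0.01 percentile. The chemokines CCL5, CXCL8 and CXCL1 had log2 ratios of -1.09, -0.93 and -0.68, and the interval of CXCL8 was -1.13 to -0.74. IL1A and the NF-kB inhibitor gene NFKBIA lay near the list median, at -0.28 and -0.20. Beside this group, the fibroblast marker list also stood apart below 0, with a median of -2.18 over 7 members, 4 of them at least 2-fold lower. The median was the same with DCN set to 3 reads in the PRMT5 overexpression library. This median was -1.43 with a prior count of 5 and -1.28 with no floor, and a floor of 50 reads left too few members for a value. These values rested on few reads, since COL1A2 had 26 and 7 reads and DCN 12 and 0. DCN was 5.53-fold lower against a floor of 3 reads, with a counting interval up to a log2 ratio of -1.94. COL1A1 with 1321 and 1557 reads had a log2 ratio of -0.23. PDGFRB, with 25 and 29 reads, was at -0.24, and MFAP5, with 12 and 21 reads, at 0.32. The single measured leukocyte marker, ITGAM, had 12 and 3 reads and a log2 ratio of -2.09, with an interval of -4.93 to -0.58, and the endothelial markers VWF and ERG were at -0.42 and -0.29.

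The median of the hypoxia and glycolysis list stood apart below 0 by a small amount. Of 33 genes, 30 had a log2 ratio below 0 and 0 differed by 1.5-fold, with a median of -0.12 at the 0 percentile. The glucose transporter SLC2A1 and the pyruvate kinase gene PKM both had log2 ratios of -0.12. The integrated stress response list had a median of -0.11 at the 0.04 percentile, with 20 of 25 members below 0. It held NUPR1 at -0.71 and SLC7A11, the cystine transporter, at -0.11.

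The TGF-beta target, beta-catenin target and squamous differentiation lists also lay on the lower side. The 23 TGF-beta target genes had a median of -0.14 at the 0.09 percentile, and ID2, an inhibitor of bHLH factors, had a log2 ratio of -1.56 and BMP2 of -0.77. Of these genes 14 were below 0, and 2 were higher and 2 lower by 1.5-fold or more. This call was lost with the mean, at the 13.4 percentile, and among genes that share no exon base with a counted gene, at the 3.18 percentile. The 20 measured beta-catenin target genes had a median of -0.17 at the 0.15 percentile, with MYC far below BIRC5, an inhibitor of apoptosis, at -0.13. The squamous differentiation list had a median of -0.14 at the 0.37 percentile, with 20 of 25 members below 0, and lay at the 2.5 percentile, no longer apart, among genes that share no exon base with a counted gene. Its members included the protease KLK10 at -0.66 and the cornified envelope protein SPRR3 at -0.62, and 2 members were higher and 3 lower by 1.5-fold or more. KRT6B, at -0.14, shares sequence with other keratin genes and is uncertain.

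The medians of the sterol biosynthesis, NRF2 target and heat shock lists stood apart above 0, with 0 members at 1.5-fold or more higher. Of 24 sterol biosynthesis genes, 21 had a log2 ratio above 0, with a median of 0.18 at the 100 percentile. FDPS and MSMO1 were at 0.19 and 0.17, while the desaturase gene SC5D was at -0.94. NRF2 target genes had a median of 0.15 at the 99.94 percentile, with 21 of 24 members above 0, AKR1B10 and GPX2 both at 0.15. Heat shock genes had a median of 0.19 at the 99.98 percentile, with 12 of 15 members above 0 and HSP90AB1 at 0.19.

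The mitochondrially encoded genes were all above 0, with a median of 0.27 over 13 members at the 100 percentile. Only 1 of them, MT-ND6 at 0.72, was higher by 1.5-fold or more. Nuclear-encoded oxidative phosphorylation genes had a median of 0.17, with 26 of 32 members above 0. Only 1, ATP5MG at 0.86, was higher by 1.5-fold or more. Of 48 ribosomal protein genes, 42 were above 0, with a median of 0.14, and 2 were higher by 1.5-fold or more. RPLP0, among these 2, was at 0.66 and shares sequence with other genes. Both lists lay at the 100 percentile. All genes of the mitochondrial genome, rRNA genes included, took 6.74% of the reads in the vector control library and 7.55% in the other. Interferon-stimulated genes had a median of 0.08 at the 98.9 percentile, although IFI27 was at 82.9 CPM against 166 CPM in the vector control. The call of this list was lost with the mean, at the 92.2 percentile, with unmatched random lists, at 95.8, and among genes that share no exon base with a counted gene, at 97.3.

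**Figure D2:**
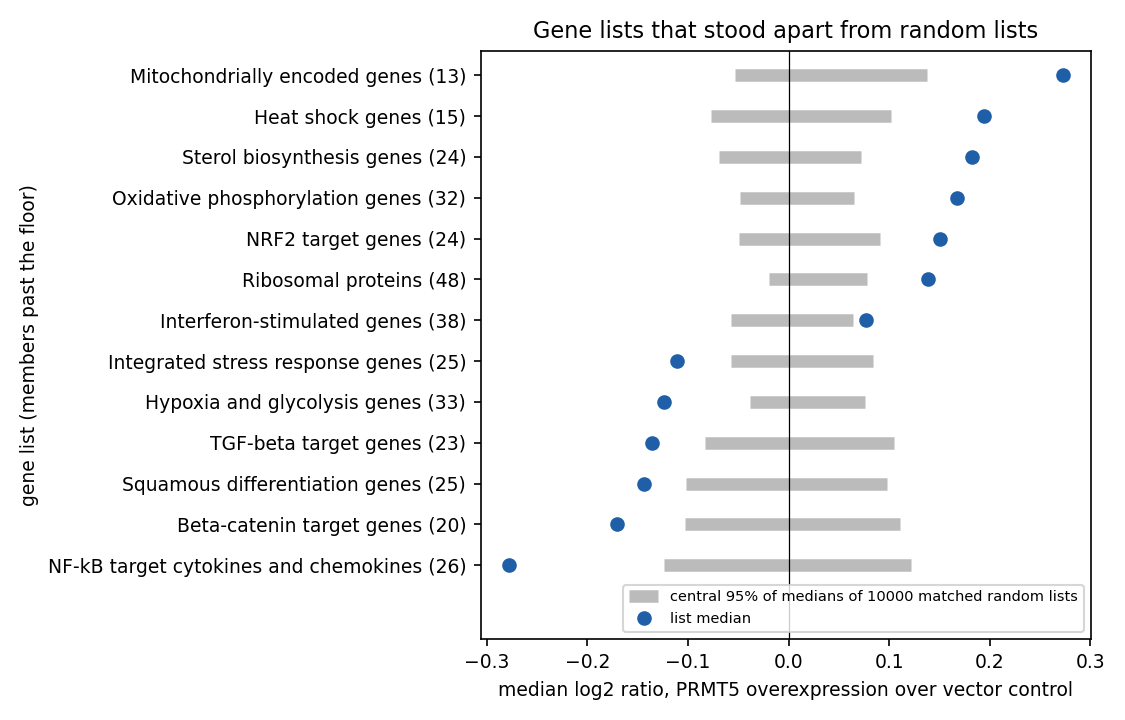
Points give the median log2 ratio of PRMT5 overexpression over vector control for each gene list that stood apart, other than the fibroblast markers, and the number after each name is its members past the floor. Grey bars give the central 95% of medians of 10000 random lists matched on expression. Medians run from -0.28 for NF-kB target cytokines and chemokines to 0.27 for mitochondrially encoded genes.

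The remaining 30 lists lay within the range of random lists matched on expression. After matching on length, GC content and expression, 4 of them lay outside, the p53 target genes at the 2.18 percentile, the growth factors and receptors at 2.05, the fatty acid synthesis genes at 98.8 and the replication-dependent histones at 0.67. MYC target genes had a median of 0.05 at the 91.2 percentile beside the low value of MYC itself. S-phase and E2F genes had a median of 0.03, and G2/M genes, with AURKA at 0.59, had a median of 0.02. The spliceosome list, whose Sm proteins are known substrates of PRMT5, had a median of 0.03, and its member SRSF2 was at 0.81. Wnt ligands and receptors had a median of -0.03, p53 target genes, with PHLDA3 at -1.09, a median of -0.08, and immediate early genes, with MYC at -3.88, PHLDA1 at -1.32 and ATF3 at 1.09, a median of -0.03. The mean over the immediate early genes was -0.15, at the 1.85 percentile, and -0.03, at the 35.3 percentile, without MYC. The apoptosis regulators had a median of -0.02, with BCL2L11, which encodes BIM, at 1.37. SRSF2 and BCL2L11 share exon bases with counted genes and had log2 ratios of 0.65 and 0.91 once summed with them. FDPS, ATP5MG, PHLDA1, ID2, KLK10, SLC2A1 and SLC7A11 share exon bases with a counted gene too, and their log2 ratios in such sums were 0.24, 0.86, -1.24, -1.51, -0.63, -0.12 and -0.11.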

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

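The settings for genes that share no exon base, genes with a mean of 50 or more reads data without mitochondrially encoded genes, random lists matched on length, GC content and expression, and the mean of the immediate early genes without MYC were chosen after seeing the data. The PRMT5 log2 ratio stayed within its counting interval under both other prior counts and under median-of-ratios size factors. The numbers of genes at least 2-fold higher and lower, 516 and 344, became 267 and 227 with a prior count of 5, 2158 and 2847 with no floor, 136 and 117 with a floor of 50 reads, 239 and 210 with protein-coding genes only, 1255 and 947 at a threshold of 1.5-fold, 93 and 107 with deposited FPKM, 284 and 204 among genes that share no exon base, and 106 and 107 among genes with a mean of 50 or more reads. The stricter sets hold fewer genes by construction. A prior count of 5 also shrinks every log2 ratio by construction, most for genes with few reads, and the pseudocount acts alike on FPKM. How much of the fall with FPKM came from its floor or from its pseudocount was not tested. Under all alternatives run for them, between 13 and 18 lists stood apart, against 14, with 18 when random lists were matched on length, GC content and expression. Of the 30 lists inside the random range, 9 stood apart under at least 1 alternative. In 160 of 166 recalculations the lists that stood apart did so the same way. Some settings could hardly change a call, as median-of-ratios size factors shift well-read genes alike, so this share does not measure robustness. The exceptions were a squamous differentiation median of -0.123 among genes that share no exon base; interferon-stimulated medians of 0.0774 with unmatched random lists and 0.0649 among genes that share no exon base, and a mean of 0.0653; and a TGF-beta target mean of -0.072 and a median of -0.0849 among genes that share no exon base. The cause was not tested. Of 414 values recalculated for 83 named genes, 410 stayed within their counting intervals and 0 changed sign where the gene was called 2-fold apart. The settings used for these values move the ratio of a well-read gene little by design. A comparison with fold changes of the authors gave no value here. No paired analysis was possible because each group has 1 library.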

Other observations

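The test of counting error for well-covered genes was chosen after the result was seen; the other tests here were set before their results, although the reading of the sums over overlapping genes was changed after they were seen. GAPDH, a gene in common use as an expression reference, had a log2 ratio of -0.08, and the median of 27 such reference genes was 0.07. Some single genes outside the list patterns differed more. TUBB3, a neuronal tubulin that also occurs in carcinoma lines, was at 1.54, although 79.3% of its tested sequence stretches occur in transcripts of other genes. HDAC3, a histone deacetylase, was at 0.62, CTNND1, which encodes the junction protein p120 catenin, at -0.74, and AJUBA, a regulator of YAP signalling, at -0.74.

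The first pattern is the 213 well-covered genes (mean of 50 or more reads) at least 2-fold apart, among them MYC. Counting error alone is argued against, since 100 simulated pairs with no difference gave at most 2 such genes. Of these genes 111, or 52.1%, share no exon base in GENCODE release 29 with a counted gene. Reads divided differently between genes that overlap in that release cannot, by definition, account for them. Sequence shared with genes elsewhere was searched for named genes only. The gene models behind the deposited counts may differ from GENCODE release 29, so overlaps outside it were not examined. The other 102 genes share exon bases, which is 47.9% of the pattern where 36.8% of all well-covered genes do so, and for them this explanation cannot be told apart from dilution: 71.6% came under 2-fold when summed with their exon-sharing genes, but so did 73.5% (median) with random partners of the same read counts, a result that the criterion set beforehand would have counted against the explanation although large partners bring any sum near 0. PRMT5 itself, or a difference between the cultures, remains open and may account for part of the pattern, as there was 1 library per group.

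The second pattern is that the mitochondrially encoded, oxidative phosphorylation and ribosomal protein lists, which hold short transcripts, had medians above 0 that stood apart together. The median log2 ratio was 0.09 in the lowest of 4 equal bins of exon length and -0.03 in the highest, so a length or GC trend across all genes might have carried them. After random lists were matched on exon length, GC content and expression in 4 bins each, all 3 lists still lay outside the central 95% of random medians. Against matching on expression alone, the upper end of that range rose from 0.137 to 0.229 for mitochondrially encoded genes. It rose from 0.0654 to 0.110 for oxidative phosphorylation genes and from 0.078 to 0.0916 for ribosomal proteins. This argues against a trend between the bins as the whole cause. A trend within a bin was left in by this matching, so its part in the medians cannot be told. A difference in growth state between the cultures, or PRMT5, was not tested and stays open.

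The third pattern is the NF-kB target cytokine and chemokine list, whose median of -0.28 stood apart below 0. A length or GC trend between the bins is argued against, as the median lay at the 0.01 percentile after the same matching. Counting error is argued against, as the central 95% of 1000 simulated pairs with no difference ran from -0.0678 to 0.0666. RNA of other cells in the vector control library was not tested, nor was an effect of PRMT5 on NF-kB. The few reads of 4 fibroblast markers and of ITGAM could be a trace of such cells, while COL1A1, PDGFRB and MFAP5 lay within 1.5-fold.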
